A study of Mus musculus with 12 samples.

How the data were processed

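RNA-seq measured the liver of C57BL/6 mice in 12 libraries, 3 in each of 4 groups: sham surgery, sham surgery with gallic acid, cecal ligation and puncture (CLP), and CLP with gallic acid. Groups and replicate numbers were read from the sample titles and treatment labels, and the replicate numbers were used only as names in the main fit. The labels do not say that each library came from its own animal, so p-values measure only the spread between these samples, which may be technical. Total RNA was isolated with TRIzol and libraries were made with a KAPA stranded kit, per the labels' protocols. The extraction text of the labels speaks of islets where the tissue label says liver. The liver label was used. Of the 18 endocrine and 20 exocrine pancreas markers written down for this question, 1 each was among the listed genes. The listed genes are a selection (below), so this count cannot tell islets from liver. In sham, Trf and Ambp, of the list of secreted hepatocyte proteins, held 6.34% and 1.82% of listed counts. The fibrinogen genes Fgg, Fgb and Fga held 3.15%, 2.71% and 2.61%. These shares argue against islets as the main source of the RNA.

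The deposited tables hold whole-number read counts per gene, identified by Ensembl gene ID, with 1 table per library. Per the submitters' processing notes, the tools were HISAT, featureCounts 1.5.0-p3 and DESeq 1.8.3, and the genome build was GRCm38. The version of HISAT, its settings, the annotation and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be told apart. Reads of near-identical family members (Saa1 and Saa2, the Orm, Mup, Hba, Gst, Ugt2b and Cyp2c families) could have been split or dropped, so values of single members are uncertain. IDs were matched to GENCODE vM21 on GRCm38 for symbols and positions, and 1323 of 1324 matched.

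Each deposited table lists the same 1324 genes, which are a selection. The order of the genes follows the p-value of a one-way F test over the 4 groups on unscaled counts, computed here from the deposited counts: 1 neighbouring pair was out of order, 1269 genes had a p-value under 0.05 and the highest p-value was 0.0543. No source states this rule. The genes were thus chosen on the same 12 libraries that are compared, so numbers of changed genes hold for this list and not for the genome, and p-values are smaller than for genes chosen without these data. The total per library is a total over listed genes and not the sequencing depth, which is not given in the sources used here. Over all 66 pairs of libraries, none had counts that were equal within sampling noise (lowest chi-square per degree of freedom 205). Among counts from 1 to 99, 38.1% were multiples of 4, where 25% would be expected, and whether low counts are unaltered read counts is not given in the sources used here.

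Counts were analysed with edgeR 4.0.16 in R 4.3.3. The filterByExpr rule left out 38 genes and 1286 were tested. Libraries were scaled with TMM factors computed on the listed genes. A quasi-likelihood fit (robust) of all 12 libraries with 1 mean per group gave 8 residual degrees of freedom, a prior of 5.1 and a common biological coefficient of variation of 0.403. The comparisons were CLP against sham, CLP with gallic acid against CLP, sham with gallic acid against sham, CLP with gallic acid against sham with gallic acid, and the difference between the last and the first CLP effect (interaction). Adjusted p is Benjamini-Hochberg over the 1286 genes, with a threshold of 0.05. Log2 fold changes carry a standard error (SE) equal to the change divided by the square root of the F statistic. Scaled counts are counts divided by the TMM effective library size and multiplied by the geometric mean of these sizes, given as mean ± SD over 3 libraries. TMM assumes that most listed genes do not change, which a list chosen for change need not meet. Under median-of-ratios scaling (the size factors of DESeq2), the median log2 change of all tested genes moved by -0.256 in CLP against sham and by -0.371 in CLP with gallic acid against sham with gallic acid.

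Gene lists of pathways, hepatocyte functions and cell type markers were written by hand: 42 lists with 986 entries, of which 216 were in the tables and 18 lists had at least 5 tested members. These 18 were compared with all other tested genes by camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, and adjusted over the 18. No list passed with an estimated correlation in any comparison, and the smallest such adjusted p was 0.229. The list of C/EBP and MAPK pathway genes, and Cebpb in the panel, were chosen knowing that a publication on gallic acid in this model concerns that pathway. Their values are not independent evidence for it.

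Genes to be named were fixed by rule: in each comparison, the 5 largest rises and 5 largest falls past the threshold with a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries, leaving out unnamed predicted genes; from each list described, the 2 to 4 members with the smallest adjusted p and any member against the list's direction; and, in CLP against sham and in CLP with gallic acid against CLP, a panel of 10 genes. Of this panel 8 were in the tables, and Jun and Alb are not analysed here. The tests, lists, panel and most alternatives were fixed before the data were examined. An edgeR fit was first seen while the tables were being described, and the alternative without any scaling was chosen after the data had been seen. Genes named outside the rule are said to be so where they appear. Some genes that the rule would name are not reported here.

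The alternatives were median-of-ratios scaling, no scaling, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 10 CPM in 3 libraries, a fold limit, fits of the 2 compared groups alone, the replicate number as a block, and leaving out each library in turn. The edgeR step was tested on simulated counts of 1286 genes with 200 changed genes, in 20 simulations per comparison. For CLP against sham it recovered 64% of 4-fold and 13.1% of 2-fold changes, and 4.22% of its calls were false. For CLP with gallic acid against CLP it recovered 63.5% of 4-fold and 11.8% of 2-fold changes, with 4.15% false. For sham with gallic acid against sham the shares were 66.2%, 10.7% and 3.6%, and for CLP with gallic acid against sham with gallic acid 62.9%, 11.4% and 4.12%. In the gallic acid comparisons, changes of 2-fold or less are therefore mostly below what 3 libraries per group can detect at this spread. In the CLP comparisons 804 and 848 genes passed, against 200 changed genes in the simulations. The adjusted threshold is then less strict, so these recovered shares need not hold there. The simulated genes were not selected as the listed genes were, so these shares of false calls need not hold for the deposited list. In 100 further simulations with that selection and no gallic acid effect, 41 gave a call in CLP with gallic acid against CLP and 45 in the interaction.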

Results

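Liver RNA was sequenced from mice that underwent sham surgery or CLP, with or without gallic acid, to ask how gallic acid alters hepatic transcripts in sepsis. CLP ties off and pierces the cecum so that gut bacteria leak into the abdomen, and is a widely used mouse model of sepsis. Gallic acid is a plant phenolic acid with antioxidant activity. The dose and schedule of gallic acid and the time between surgery and sampling are not given in the sources used here. Counts over the 1324 listed genes came to 10150277 to 11961679 per library in sham, 10967313 to 11543000 in sham with gallic acid, 18891693 to 22032386 in CLP and 17526232 to 23852828 in CLP with gallic acid. The 10 most abundant listed genes took 37 to 42% of these counts in sham and 62.5 to 65.4% in CLP, where Hpx rose from 3.18 to 11.5%, Hp from 1.57 to 10.3% and Saa1 from 0.229 to 7.61% of listed counts. Replicates of a group correlated at r = 0.955 to 0.977 across genes.

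The first principal component held 66.4% of the variance and separated the 6 CLP libraries from the 6 sham libraries. It placed 2 libraries between these sets: CLP with gallic acid replicate 7, at 16.3 against 32.6 to 39.2 for the other CLP libraries, and sham replicate 4, at -23.3 against -38.1 to -32.8 for the other libraries without CLP. In sham replicate 4 the serum amyloid Saa1 stood at 66130 scaled counts, against 1839 and 4497 in the other sham libraries. In CLP with gallic acid replicate 7 it stood at 749600, against 1572000 and 1594000 in the others of that group.

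**Figure D1:**
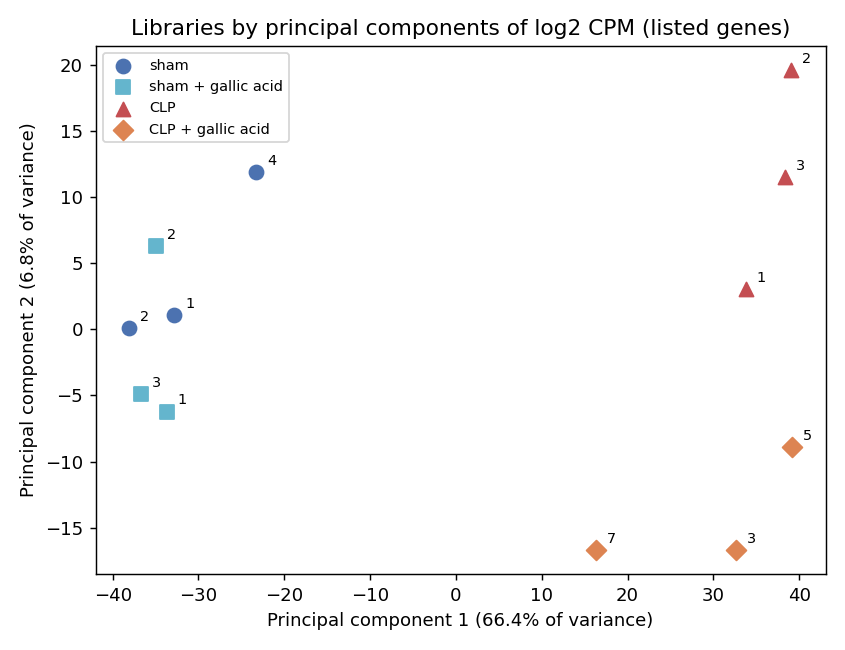
Each point is 1 of the 12 libraries, placed by its principal components of log2 CPM over the listed genes (axes without units, with the share of variance), coloured by group and numbered by replicate. The 6 CLP libraries lie at 16.3 to 39.2 on component 1 and the 6 libraries without CLP at -38.1 to -23.3.

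Transcripts of acute-phase and metal-binding proteins rose in CLP liver. The largest rise of a named gene was that of metallothionein Mt2 (ENSMUSG00000031762, chromosome 8, 94172664 to 94173568, GRCm38), a zinc-binding protein, from 131 ± 134 to 56270 ± 8423 scaled counts (mean ± SD, n = 3 each), a log2 change of 8.74 ± 0.96 (SE; edgeR adjusted p = 6.88e-05). Its neighbour Mt1 (chromosome 8, 94179082 to 94180327) rose 177-fold (adjusted p = 2.43e-05). Among the 5 largest rises were also Lcn2, an iron-siderophore binding protein, by 7.04 ± 1.30 on the log2 scale, the chitinase-like Chil1 by 7.05 ± 0.92 and the cell surface protein Igdcc4 by 7.68 ± 1.09. The largest falls were those of the pseudogene Mup-ps16, the carbonic anhydrases Car3 and Car1, Clec2h and the transcription factor Pitx3. Car3 (chromosome 3, 14863512 to 14872523) went from 236900 ± 49030 to 1777 ± 1485 scaled counts (log2 change -7.06 ± 1.22, adjusted p = 0.000845). Clec2h changed by -6.51 ± 1.58, Pitx3 by -5.02 ± 0.96 and Car1 by -4.82 ± 1.35. Mup-ps16 had 698 counts over the sham libraries and 2 over the CLP libraries, a ratio of 312 (95% counting interval 86.2 to 2580, counting error only and only if low counts are unaltered read counts). Single libraries moved some of these log2 changes: without sham replicate 4 they were 9.96 for Mt2, 10.06 for Lcn2 and 8.03 for Chil1, without sham replicate 2 6.45 for Chil1 and -7.32 for Mup-ps16, without CLP replicate 1 -7.96 for Car3 and -11.82 for Car1, without CLP replicate 2 -10.84 for Mup-ps16, and without CLP replicate 3 6.39 for Chil1 and -6.47 for Pitx3.

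All 26 tested members of the acute-phase list rose with CLP (camera adjusted p = 1.98e-14; adjusted p = 0.233 with an estimated correlation). The pentraxin Apcs rose 38.7-fold to 256600 ± 79880 scaled counts, the fibrinogen-like Fgl1 11.1-fold and the inter-alpha-trypsin inhibitor chain Itih3 7.2-fold (adjusted p = 5.2e-05, 5.45e-05 and 6.28e-05). Saa1 (chromosome 7, 46740497 to 46742980) went from 24160 ± 36380 to 1693000 ± 226700, a log2 change of 6.13 ± 1.14 with an adjusted p of 0.00116. Sham replicate 4 carries that sham mean, and without it the log2 change of Saa1 was 9.05. All 10 members of the iron and metal list rose as well (camera adjusted p = 5.29e-05; adjusted p = 0.233 with an estimated correlation). Beside both metallothioneins, which the lists share, they included the heme scavenger Hpx, at 7.62-fold, and Hamp, which encodes the iron hormone hepcidin, at 3.81-fold. Of 5 glucocorticoid targets 4 rose (camera adjusted p = 0.00208; adjusted p = 0.254 with an estimated correlation), among them Fkbp5 at 7.04-fold and the estrogen sulfotransferase Sult1e1 at 26.2-fold, beside Mt1 and Mt2. The log2 change of Sult1e1, 4.71 ± 1.23, was 6.86 without sham replicate 4 and 3.85 without CLP replicate 2.

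Of 8 listed cytokines and chemokines 4 rose (camera adjusted p = 0.0229; adjusted p = 0.254 with an estimated correlation): the neutrophil chemokine Cxcl1 from 698 ± 434 to 15190 ± 943 scaled counts (21.8-fold, adjusted p = 6.28e-05), Cxcl14 12.6-fold, Cxcl2 6.16-fold and Ccl6 5.93-fold. Il1b was at 217 ± 38.4 and 246 ± 37.6 (log2 change 0.18 ± 0.40, adjusted p = 0.695; -0.10 under median-of-ratios scaling). The interferon-induced Cxcl10 was at 262 ± 85.3 in sham and 120 ± 82 in CLP. Its log2 change of -1.12 ± 0.47 had an adjusted p of 0.0503 and passed without CLP replicate 1 (adjusted p = 0.0117), under median-of-ratios scaling (0.0162), without scaling (0.0337) and in DESeq2 (0.00573). Of 8 NF-kB targets 6 rose (camera adjusted p = 0.026; adjusted p = 0.285 with an estimated correlation), among them the feedback regulators Nfkbiz (3.56-fold), Tnfaip3 (4.91-fold) and Irak3 (5.68-fold). Of 7 C/EBP and MAPK genes 6 rose (camera adjusted p = 0.026; adjusted p = 0.233 with an estimated correlation). The transcription factors Cebpd and Cebpb rose 4.8-fold and 2.89-fold (adjusted p = 0.000215 and 0.00895), and the kinases Map3k14 and Map3k8 3.33-fold and 2.47-fold, while the kinase Map2k6 had a log2 change of -0.29 ± 0.57 (adjusted p = 0.659; 0.27 without sham replicate 1). Without sham replicate 4 the log2 changes were 5.08 for Cxcl1, 3.40 for Irak3 and 2.31 for Cebpb, against 4.44, 2.51 and 1.53 with it.

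Of 6 immediate-early genes 5 rose (camera adjusted p = 0.0229; adjusted p = 0.233 with an estimated correlation), with Junb at 4.11-fold and Ier5 at 3.05-fold. Of 6 JAK-STAT3 genes 4 rose and 1 fell, and the list did not pass (camera adjusted p = 0.0592; adjusted p = 0.254 with an estimated correlation), though it did without sham replicate 4 (0.0294), CLP replicate 1 (0.0445) or CLP with gallic acid replicate 7 (0.0433). The cytokine signalling inhibitor Socs3 rose 18.9-fold (adjusted p = 5.2e-05) and the oncostatin M receptor Osmr 3.59-fold, and the LIF receptor Lifr fell by 1.03 ± 0.32 on the log2 scale (adjusted p = 0.0147; 0.0524 without sham replicate 4). Chac1, a glutathione-degrading enzyme induced in the unfolded protein response, was the only tested member of the ER stress list and rose from 145 ± 12 to 1397 ± 185 scaled counts (log2 change 3.26 ± 0.32, adjusted p = 5.2e-05).

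Of 16 drug-metabolism genes 11 fell and 2 rose (camera adjusted p = 0.0111; adjusted p = 0.254 with an estimated correlation). Cyp3a11, a main xenobiotic-oxidising cytochrome, went from 290100 ± 80570 to 20730 ± 7961 scaled counts (log2 change -3.81 ± 0.47, adjusted p = 0.000128), and the glucuronosyltransferase Ugt2b1 fell by 3.38 ± 0.58 on the log2 scale. Against the list, Cyp3a13 rose 3.53-fold and Cyp2c38 3.37-fold, and Cyp2c37 had a log2 change of 0.02 ± 0.27 (adjusted p = 0.941), negative under both other scalings. Of 11 NRF2 and antioxidant genes 10 fell (camera adjusted p = 0.00343; adjusted p = 0.254 with an estimated correlation), with the glutathione transferases Gstp1 and Gsta2 at log2 changes of -1.76 ± 0.28 and -3.45 ± 0.63 and the aldehyde oxidase Aox1 at -1.14 ± 0.24. The heme oxygenase Hmox1 rose against them, 2.7-fold (adjusted p = 0.00248). Of 5 bile acid genes 3 fell (camera adjusted p = 0.0308, lost without CLP replicate 3 at 0.0535; adjusted p = 0.254 with an estimated correlation): the conjugating enzyme Baat, the transporter Slco1a1 and the sterol hydroxylase Cyp8b1, at log2 changes of -1.36 ± 0.26, -3.66 ± 0.80 and -2.02 ± 0.45. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 6581 ± 986 in sham and 7366 ± 3982 in CLP (log2 change 0.16 ± 0.36, adjusted p = 0.698), and its sign turned under median-of-ratios scaling (-0.13), without scaling (-0.01) and without CLP replicate 1 (-0.23). The log2 change of Gsta2 was -2.72 without sham replicate 1, and those of Ugt2b1 and Slco1a1 were -4.11 and -4.26 without CLP replicate 1.

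Of 7 glucose-metabolism genes 6 fell (camera adjusted p = 0.0159; adjusted p = 0.254 with an estimated correlation), among them the pyruvate kinase Pklr (log2 change -1.81 ± 0.35) and the glycogen-targeting Ppp1r3c (-1.40 ± 0.37). All 8 autosomal genes of the male-biased hepatocyte list fell (camera adjusted p = 0.000113; adjusted p = 0.233 with an estimated correlation), with the fatty acid elongase Elovl3 at -3.86 ± 0.65, Ugt2b38 at -1.58 ± 0.32 and the urinary protein Mup20 at -2.07 ± 0.42, beside Gstp1. Without CLP replicate 3 the log2 changes were -2.02 for Ppp1r3c and -4.69 for Elovl3.

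Most listed markers of myeloid cells also rose. Of 8 neutrophil markers 7 rose (camera adjusted p = 0.011; adjusted p = 0.254 with an estimated correlation), among them Retnlg at 28-fold and the integrin Itgb2 at 2.97-fold, and Lcn2, which hepatocytes also secrete. All 4 Kupffer cell markers rose, with the scavenger receptor Marco at 18.1-fold and Timd4 at 2.59-fold, and 7 of 10 monocyte and macrophage markers (camera adjusted p = 0.0255; adjusted p = 0.254 with an estimated correlation), with Lgals3 at 3.21-fold, Plac8 at 2.81-fold and Chil3 at 30.8-fold (log2 change 4.95 ± 1.14, 7.88 without sham replicate 4 and 4.34 without sham replicate 1).

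In total 804 of 1286 tested genes passed in CLP against sham by edgeR, 472 higher and 332 lower, and 677 of them changed at least 2-fold. These genes had been listed for differing among these libraries. The balance depends on the scaling: 58.7% of calls were higher with TMM, and median-of-ratios scaling gave 378 higher and 417 lower. By camera 14 of 18 lists passed, 9 up and 5 down, and none with an estimated correlation (smallest adjusted p = 0.233). Adjusted over the list alone, 6 cytokines and chemokines, 6 immediate-early genes and 8 monocyte and macrophage markers passed, and the numbers of the other lists that passed by camera stayed as they were. Of the complement list, which did not pass by camera, 5 genes passed in this way and 4 over all genes.

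**Figure D2:**
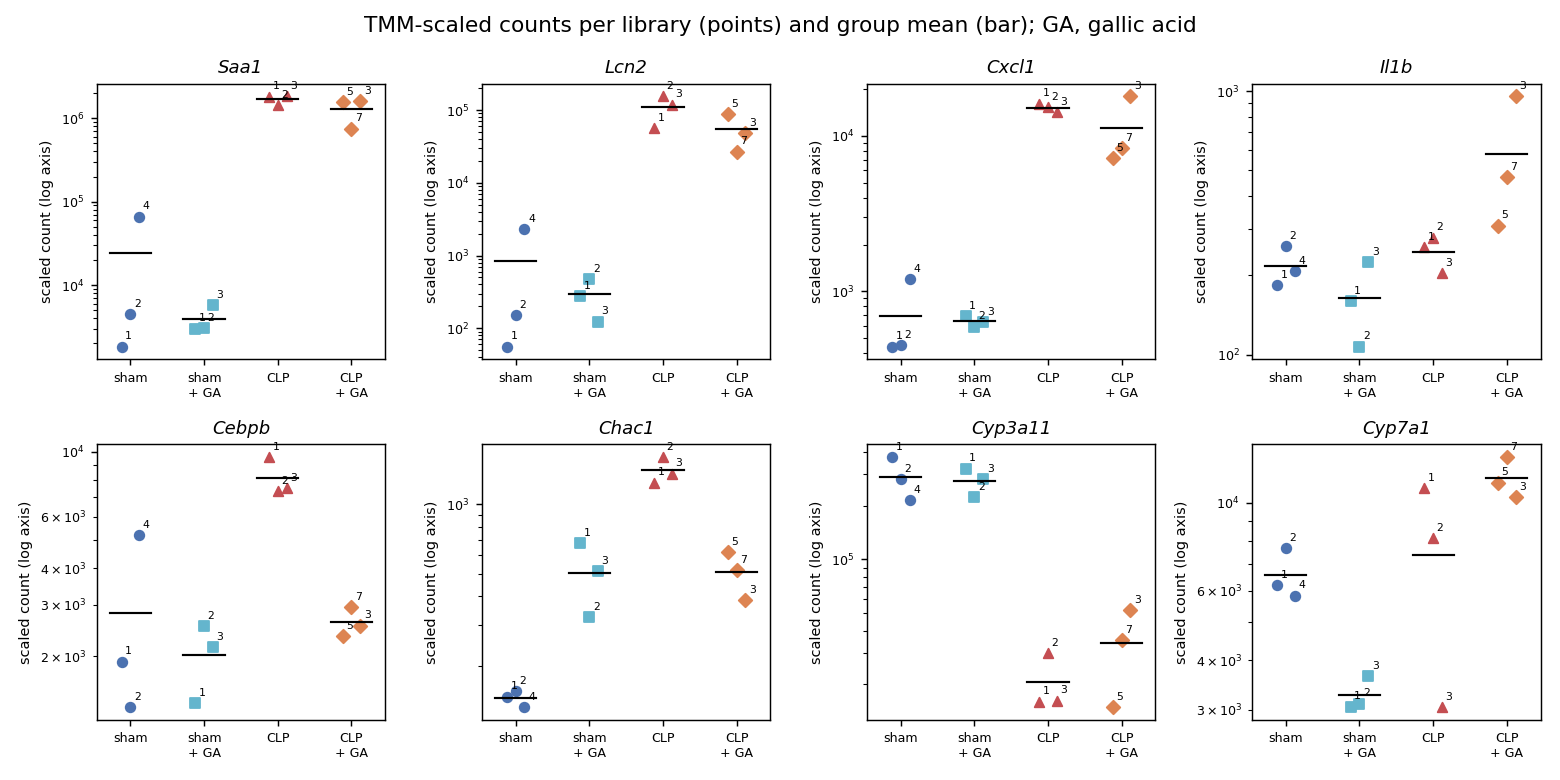
Scaled counts (log axis) of 8 genes in each library, numbered by replicate, with the group mean as a bar; GA is gallic acid. Saa1, Lcn2 and Cxcl1 lie higher in every CLP library than in every library without CLP, Cebpb stands at 2350 to 2954 in CLP with gallic acid and at 7327 to 9600 in CLP, and Chac1 is lowest in sham, at 132.6 to 156.3.

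Gallic acid given to CLP mice is the comparison the series title names. No gene passed the threshold in edgeR. The transcription factor Cebpb, in the panel, stood at 8141 ± 1266 scaled counts in CLP and 2618 ± 308 in CLP with gallic acid (log2 change -1.64 ± 0.43, unadjusted p = 0.00206, adjusted p = 0.158), with every treated library below every untreated one. Chac1 stood at 1397 ± 185 and 508 ± 119 (log2 change -1.46 ± 0.30, adjusted p = 0.133). Il1b was at 246 ± 37.6 and 579 ± 337 (1.24 ± 0.41, adjusted p = 0.29), against the direction of Cebpb. The remaining panel genes had adjusted p from 0.479 to 0.887: log2 changes were -0.38 ± 0.91 for Saa1, -1.02 ± 1.01 for Lcn2, -0.44 ± 0.41 for Cxcl1, -0.35 ± 0.30 for Hmox1, 0.72 ± 0.42 for Cyp3a11 and 0.65 ± 0.36 for Cyp7a1.

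By edgeR 0 of 1286 genes passed, 156 had an unadjusted p under 0.05 (79 higher, 77 lower) and the smallest adjusted p was 0.133. DESeq2 called 26 genes (7 higher, 19 lower) and limma-voom 0. Among the calls of DESeq2 were Chac1 (log2 change -1.49, adjusted p = 0.00366) and Cebpb (-1.65, adjusted p = 0.0136). Picked after their values had been seen, its calls also held the corepressor Hr (-2.79), the alpha-arrestin Arrdc3 (2.28), the RNA-binding Rc3h2 (0.97) and the casein kinase Csnk1g1 (-2.34). In edgeR these had unadjusted p of 0.000286, 0.00123, 0.000542 and 0.000637. Csnk1g1 passed in edgeR when CLP with gallic acid replicate 7 was left out (adjusted p = 0.0195).

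Of the 18 lists, the male-biased hepatocyte genes passed in camera, upwards (adjusted p = 0.0295; adjusted p = 0.803 with an estimated correlation). All 8 members had positive log2 changes, with Mup20 at 1.08 ± 0.41, the peroxisomal Nudt7 at 1.25 ± 0.48, the steroid dehydrogenase Hsd3b5 at 2.16 ± 0.84 and Ugt2b38 at 0.75 ± 0.31, and none passed alone. The call was lost without CLP with gallic acid replicate 7 (adjusted p = 0.529), the library nearest to sham on component 1, and without CLP replicate 2 (0.351). Of 26 acute-phase genes 2 had positive log2 changes (median -0.36, camera adjusted p = 0.0999, and 0.803 with an estimated correlation), with Saa3 at -1.70 ± 0.61, Serpina3n at -0.93 ± 0.56 and the haptoglobin gene Hp at -0.68 ± 0.42, and none passed. That list passed without sham replicate 4 (adjusted p = 0.0345), CLP replicate 1 (0.0278) or CLP with gallic acid replicate 5 (0.00339). Without CLP with gallic acid replicate 7 no list passed, and the smallest camera adjusted p of any list was 0.529. Of 16 drug-metabolism genes 14 had positive changes (camera adjusted p = 0.0999, and 0.803 with an estimated correlation), with Cyp2c37 at 0.54 ± 0.27 and Ugt2b5 at 0.63 ± 0.34. It passed without CLP with gallic acid replicate 5 (adjusted p = 0.00274) and stood at 0.682 without replicate 7. Of 5 bile acid genes 4 were positive (camera adjusted p = 0.159, and 0.803 with an estimated correlation), with Baat at 0.65 ± 0.26 and Slco1a1 at 1.49 ± 0.74.

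The C/EBP and MAPK list had a median log2 change of -0.42 (camera adjusted p = 0.287, and 0.803 with an estimated correlation), with Map3k14 at -0.51 ± 0.26 and Cebpd at -0.42 ± 0.30 beside Cebpb. Adjusted over the list alone, Cebpb passed (adjusted p = 0.0144), which is not independent evidence given how the list was chosen. So did Ddit4, an inhibitor of mTORC1 signalling, among p53 targets (log2 change -1.06 ± 0.34, adjusted p = 0.017 over the list alone and 0.278 over all genes). NF-kB targets (camera adjusted p = 0.607) had a median of -0.13, or 0.04 without scaling, with Tnfaip3 at -1.10 ± 0.47. Among myeloid markers Itgb2 was at -0.52 ± 0.28, Csf3r at -0.61 ± 0.36, the chemokine receptor Cx3cr1 at -1.30 ± 0.41 and Gpnmb at -2.54 ± 1.07, and neither the neutrophil list (camera adjusted p = 0.361) nor the monocyte and macrophage list (0.415) passed. Positive log2 changes were found in 2 of 8 neutrophil and 4 of 10 monocyte and macrophage markers, and the median of the latter was -0.10, or 0.05 without scaling.

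In sham mice, gallic acid was compared with sham alone, and here too no gene passed in edgeR. The smallest adjusted p was that of Chac1 (ENSMUSG00000027313, chromosome 2, 119351229 to 119354381), at 145 ± 12 scaled counts in sham and 505 ± 176 in sham with gallic acid (log2 change 1.79 ± 0.31, adjusted p = 0.0711). It passed without sham with gallic acid replicate 2 (adjusted p = 0.0178) and without CLP with gallic acid replicate 5 (0.0457), which enters through the shared spread. Among drug-metabolising cytochromes, Cyp2c38 stood at 806 ± 236 and 1830 ± 737 (log2 change 1.18 ± 0.33), Cyp2c37 at 13300 ± 2371 and 26000 ± 2707 (0.97 ± 0.28) and Cyp2c54 at 0.93 ± 0.37 on the log2 scale, with adjusted p of 0.291, 0.291 and 0.428. The mitotic Cdc20 was at 140 ± 39.7 and 29.4 ± 8.05 (log2 change -2.25 ± 0.51, adjusted p = 0.235).

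By edgeR 0 of 1286 genes passed, 122 had an unadjusted p under 0.05 (43 higher, 79 lower), DESeq2 called 9 (4 higher, 5 lower, with Chac1 at adjusted p = 3.66e-05 and Cdc20 at 0.00865) and limma-voom 0. Of the lists, drug metabolism passed upwards (camera adjusted p = 0.0366; adjusted p = 0.986 with an estimated correlation), and 14 of its 16 members had positive changes. It was lost without sham replicate 1 (adjusted p = 0.12), sham replicate 4 (0.249), sham with gallic acid replicate 2 (0.0983) or sham with gallic acid replicate 3 (0.0938). Adjusted over the list alone, Cyp2c37 and Cyp2c38 passed (0.0306 each, against 0.291 each over all genes), as did Cdc20 (0.00146 against 0.235) and Ccnb1 (log2 change -1.96 ± 0.89, 0.0468 against 0.523) among 2 proliferation genes, the glucocorticoid-induced kinase Sgk1 (-0.89 ± 0.26, 0.0252 against 0.291) and Cx3cr1 among macrophage markers (-1.74 ± 0.44, 0.0159 against 0.266). Cyp7a1 stood at 6581 ± 986 and 3274 ± 328 (log2 change -1.01 ± 0.37, adjusted p = 0.363). The log2 changes of Saa1 and Saa2, -2.62 ± 0.96 and -3.39 ± 1.16, turned to 0.30 and 0.46 without sham replicate 4, where the acute-phase list, at a camera adjusted p of 0.973 with all libraries, passed (0.00603).

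CLP under gallic acid, against sham with gallic acid, again raised acute-phase transcripts and lowered most listed drug-metabolism and antioxidant transcripts. The largest rises were those of Saa2 (log2 change 9.41 ± 1.52), Mt2 (8.80 ± 0.96), Saa1 (8.37 ± 1.25), Orm2 (7.62 ± 1.24) and Lcn2 (7.54 ± 1.33), with adjusted p from 9.79e-05 to 0.00124. The largest falls were those of Car3 (-5.02 ± 1.11), Mup-ps16 (-5.02 ± 0.99), Pitx3 (-4.41 ± 0.95), Car1 (-4.24 ± 1.29) and Elovl3 (-3.54 ± 0.64), with adjusted p from 0.00127 to 0.0147. Car1 did not pass without CLP with gallic acid replicate 3 (adjusted p = 0.0552). Without CLP with gallic acid replicate 7 the log2 changes were -7.27 for Car3, -6.81 for Mup-ps16, -6.42 for Car1 and -4.16 for Elovl3, without replicate 5 of that group -4.43 for Mup-ps16 and -3.64 for Car1, and without sham with gallic acid replicate 2 9.65 for Mt2. Cyp7a1 rose from 3274 ± 328 to 11550 ± 1385 scaled counts (3.53-fold, adjusted p = 0.00256). Of the 5 bile acid genes it was the only 1 to rise, and 4 fell. That list did not pass (camera adjusted p = 0.179, and 0.322 with an estimated correlation). Chac1 was at 505 ± 176 and 508 ± 119 (log2 change 0.01 ± 0.30, adjusted p = 0.979, and -0.36 under median-of-ratios scaling).

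All 26 acute-phase genes rose (camera adjusted p = 3.03e-12; adjusted p = 0.229 with an estimated correlation), with Mt1 at 165-fold, Fgl1 at 12.2-fold and Apcs at 31.4-fold. Of 8 cytokines and chemokines 7 rose (camera adjusted p = 0.00694; adjusted p = 0.229 with an estimated correlation), with Cxcl1 at 17.4-fold, Ccl6 at 6.25-fold and Il1b at 3.53-fold (adjusted p = 0.00383). Of 8 NF-kB targets 6 rose (camera adjusted p = 0.0224; adjusted p = 0.282 with an estimated correlation), with Nfkbiz at 4.09-fold and Irak3 at 6.28-fold, and of 6 JAK-STAT3 genes 4 (camera adjusted p = 0.0257; adjusted p = 0.229 with an estimated correlation), with Socs3 at 14.2-fold. Of 7 C/EBP and MAPK genes 5 rose and 1 fell (camera adjusted p = 0.126; adjusted p = 0.229 with an estimated correlation): Cebpd rose 3.1-fold and the stress-induced Gadd45b 4.24-fold (log2 change 2.08, or 2.70 without sham with gallic acid replicate 2), and Map2k6 fell by 2.08 ± 0.59 on the log2 scale (adjusted p = 0.0105). Of 16 drug-metabolism genes 10 fell and 1 rose (camera adjusted p = 0.00515; adjusted p = 0.229 with an estimated correlation), with Cyp3a11 at a log2 change of -3.02 ± 0.45 and Cyp3a13 at 3.07-fold higher. Of 11 NRF2 and antioxidant genes 10 fell (camera adjusted p = 0.0026; adjusted p = 0.229 with an estimated correlation), with Gsta2 at -3.43 ± 0.63 and Gstm3 at -2.74 ± 0.53, and Hmox1 rose 2.58-fold. Of 8 male-biased genes 6 fell (camera adjusted p = 0.00694; adjusted p = 0.229 with an estimated correlation), with Gstp1 at -1.17 ± 0.28. All 8 neutrophil markers rose (camera adjusted p = 0.0167; adjusted p = 0.229 with an estimated correlation), with Retnlg at 9.33-fold and Itgb2 at 2.23-fold. Of 10 monocyte and macrophage markers 9 rose (camera adjusted p = 0.0257; adjusted p = 0.253 with an estimated correlation), with Ms4a6c at 3.41-fold and Cx3cr1 at 3.47-fold. Under median-of-ratios scaling 5 neutrophil and 5 monocyte and macrophage markers rose. With that scaling 5 cytokines and chemokines rose and 1 fell, and 5 NF-kB targets and 4 C/EBP and MAPK genes rose. Falls were then 14 among drug-metabolism genes and 7 among male-biased genes.

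By edgeR 848 of 1286 genes passed, 501 higher and 347 lower. Median-of-ratios scaling gave 316 higher and 443 lower. By camera 14 of 18 lists passed, 9 up and 5 down, and none with an estimated correlation (smallest adjusted p = 0.229). Adjusted over the list alone, 8 cytokines and chemokines, 7 NF-kB targets, 5 JAK-STAT3 genes, 6 immediate-early genes and 10 iron and metal genes passed, where 7, 6, 4, 5 and 9 had passed over all genes.

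The CLP effects without and with gallic acid share no library and could be compared directly. Of the genes called in each, 618 were called in both, where independent lists would share 530, and all 618 had the same direction, against 273 for lists independent in direction as well. The genes were listed for differing among these same libraries, which can favour genes with a like CLP effect in both. The values 530 and 273 do not allow for that, so part of the likeness may follow from the selection. Across the 1286 genes, which are not independent replicates, the log2 changes correlated at r = 0.803, with a slope of 0.953 (jackknife SD 0.296) of the effects with gallic acid on those without. Leaving out 1 library gave slopes from 0.81 to 1.137. The jackknife SD takes all 12 of these slopes together, so it also holds differences between the 4 groups and may be too wide. By edgeR no gene was called in CLP with gallic acid against CLP. Genes called in CLP against sham could therefore have no opposite call there. By DESeq2, 12 genes called in CLP against sham had an opposite call and 1 a call in the same direction.

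**Figure D3:**
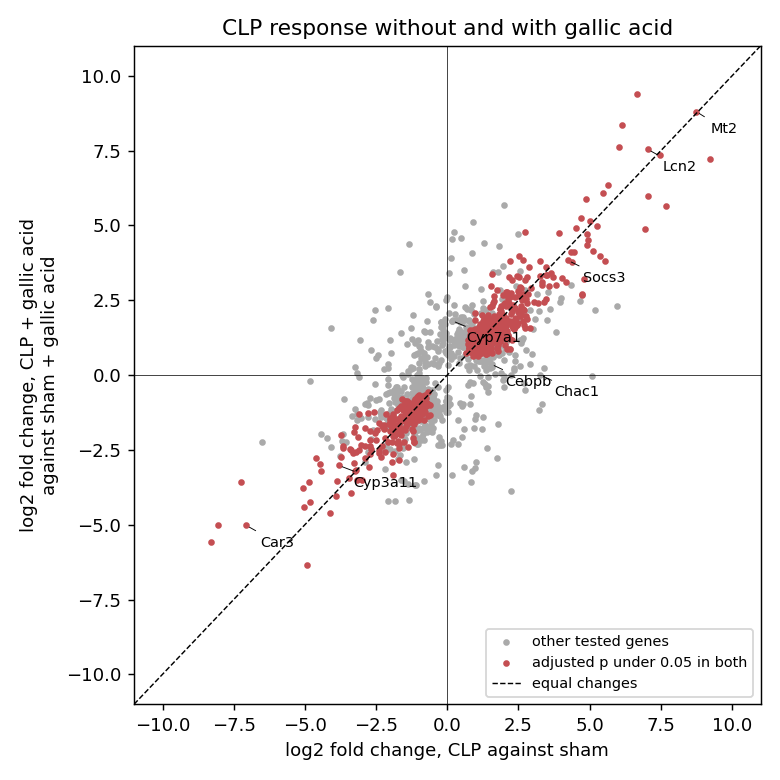
Each point is 1 of the 1286 tested genes, with its log2 fold change in CLP against sham on the horizontal axis and in CLP with gallic acid against sham with gallic acid on the vertical axis; the dashed line marks equal changes. Red points are the 618 genes with an adjusted p under 0.05 in both, and Chac1, at 3.26 and 0.01, is the labelled gene farthest from the line.

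Whether the CLP effect differed with gallic acid was tested as an interaction. Chac1 passed alone: CLP raised it by 3.26 ± 0.32 on the log2 scale without gallic acid and changed it by 0.01 ± 0.30 with gallic acid, a difference of -3.25 ± 0.43 (adjusted p = 0.00498). With the replicate number as a block, CLP with gallic acid rests on replicate 3 alone. The log2 difference was then -3.58, and the call could not be judged there. By edgeR 134 genes had an unadjusted p under 0.05, and DESeq2 called 7 genes (2 higher, 5 lower). The difference was 1.66 ± 0.52 for Cyp7a1 (unadjusted p = 0.00679, adjusted p = 0.304, and 0.0339 over the bile acid list alone), 1.64 ± 0.57 for Il1b (adjusted p = 0.31), -1.16 ± 0.59 for Cebpb (adjusted p = 0.53) and 0.95 ± 0.75 for Arrdc3 (adjusted p = 0.713). The mitotic Cdc20 passed over the proliferation list alone (0.0444) and not over all genes (adjusted p = 0.408). No list passed by camera, and the smallest adjusted p was that of the male-biased genes (0.0878; adjusted p = 0.946 with an estimated correlation). That list passed when any 1 of 5 libraries was left out (adjusted p 0.00193 to 0.0498), and the acute-phase list (0.46) without sham replicate 4 (0.00019) or CLP with gallic acid replicate 5 (0.0474). Without CLP with gallic acid replicate 7 no list passed in the interaction, and the smallest camera adjusted p was 0.718.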

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

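The count of label splits for the interaction, the selection test, the scaling test and the test of single libraries for Chac1 were all fixed before their results were seen.

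Chac1 was singled out because its response to CLP differed between mice without and with gallic acid, by the interaction test of edgeR (log2 difference -3.25 ± 0.43, adjusted p = 0.00498). With the replicate number as a block, which leaves 3 residual degrees of freedom, it did not pass in edgeR (log2 difference -3.58, adjusted p = 0.55). CLP raised it 9.6-fold without gallic acid, and with gallic acid it was at 505 ± 176 scaled counts in sham and 508 ± 119 in CLP, between the untreated sham at 145 ± 12 and the untreated CLP group at 1397 ± 185. The tables argue against the scaling of the libraries as the cause, since the highest adjusted p under the other scalings was 0.0149, and against any single library, since the highest adjusted p with 1 library left out was 0.0314. Selection of the listed genes on these libraries stays open: simulations without a gallic acid effect and with that selection gave a call in the interaction in 45 of 100, and a p as small as that of Chac1 in 6 of 100. Those simulations called 945 to 1020 genes in CLP against sham, above the 804 observed, so they match the data only in part. Other groupings of the libraries stay open too, since 21 of 100 splits of the gallic acid labels gave as many calls, with 3 as the highest number in another split, so that a gallic acid effect on Chac1 that depends on CLP is a hypothesis that these libraries cannot settle.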

How the results depend on the processing

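The alternative without scaling was chosen after the data had been seen, and all others were planned. The 804 and 848 calls of the CLP comparisons stayed within 1.5 times under other scalings, filters, DESeq2, limma-voom and 2-group fits. Of 117 named results past the threshold, all 117 kept direction and call without scaling and under median-of-ratios scaling, as did all 111 with an adjusted p in DESeq2 and 111 when each library was left out in turn. With the replicate block, which leaves fewer residual degrees of freedom, 79 of the 83 named calls in CLP against sham kept both. Calls that involve CLP with gallic acid are not compared there, since that group then rests on 1 library. The DESeq2 fit gave no adjusted p for 9 of 172 named results (Saa1, Saa2, Car3 and Clec2h, 6 of them calls in edgeR), and these are not compared. Depth is unknown, and at this spread 2-fold changes were called in 10.7 to 13.1% of simulated cases, so effects of gallic acid of that size could be missed. Alternatives for normalized values (pseudocount, filter on FPKM) were not run, since the files hold counts.

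With an estimated inter-gene correlation, camera called 0 lists in CLP against sham, 0 in CLP with gallic acid against CLP, 0 in sham with gallic acid against sham and 0 in CLP with gallic acid against sham with gallic acid (smallest adjusted p 0.233, 0.803, 0.986 and 0.229), because the wider correlation enters the variance. With 10 CPM in 3 libraries the called lists were 8, 2 and 2 in the first 3 of these comparisons and 1 in the interaction, with fewer genes tested. DESeq2 called 26 genes in CLP with gallic acid against CLP, 9 in sham with gallic acid against sham and 7 in the interaction. By DESeq2, 12 genes changed by CLP had an opposite call in CLP with gallic acid against CLP, which shares the CLP libraries with opposite sign. The cause was not tested.

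With 1 library left out, genes called were 639 to 816 in CLP against sham, 0 to 1 in CLP with gallic acid against CLP, 0 to 3 in sham with gallic acid against sham, 607 to 852 in CLP with gallic acid against sham with gallic acid and 1 to 2 in the interaction. Called lists were 13 to 16, 0 to 3, 0 to 2, 14 to 14 and 0 to 2 in the same order. Genes with such opposite calls were 0 to 1, and the slope was 0.81 to 1.137.

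Directions reversed only in results that had not passed, and the cause was not tested. In CLP against sham, Il1b went to -0.10 under median-of-ratios scaling and in DESeq2, Cyp7a1 to -0.13 in both and -0.01 without scaling, and Cyp2c37 to -0.26 in both and -0.15 without scaling. Chac1 in CLP with gallic acid against sham with gallic acid went to -0.36 under median-of-ratios scaling and in DESeq2. With 1 library left out, the ranges that crossed 0 were -0.23 to 0.53 for Cyp7a1, -0.16 to 0.18 for Cyp2c37 and -1.05 to 0.27 for Map2k6 in CLP against sham, -0.23 to 0.28 for Chac1 in CLP with gallic acid against sham with gallic acid, and -3.175 to 0.305 for Saa1 and -3.959 to 0.462 for Saa2 in sham with gallic acid against sham.

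Whether the replicate numbers pair the libraries could not be settled. Over 9 same-numbered pairs the residual correlation was -0.112 to 0.216, with 2 over 0.1. Of the 12 libraries 5 correlated best with a library of their own number. Sham replicate 4 and CLP with gallic acid replicates 5 and 7 had no same-numbered partner and could not do so. With the replicate block, which leaves 3 residual degrees of freedom, 678 genes were called in CLP against sham, 1 in CLP with gallic acid against CLP, 359 in CLP with gallic acid against sham with gallic acid and 1 in the interaction, and 1 list was called in the interaction. Calls that ended under the block in CLP against sham were those of Lifr, Cyp8b1, Ifit3b and Timp1 (edgeR adjusted p 0.106, 0.0523, 0.0735 and 0.0953). In CLP with gallic acid against sham with gallic acid, log2 changes were -4.70 for Car1, -1.25 for Gstp1 and 1.69 for Cx3cr1. Those of Map2k6 and Gadd45b were -2.37 and 1.99. The interaction of Chac1 had a log2 difference of -3.58 against -3.25 without the block. Under the block the log2 change was -0.047 for Cyp2c37 in CLP against sham, 0.30 for Cxcl1, 0.20 for Hmox1 and 0.02 for Tnfaip3 in CLP with gallic acid against CLP, 0.135 for Saa1 and 0.231 for Saa2 in sham with gallic acid against sham, and -0.37 for Chac1 in CLP with gallic acid against sham with gallic acid.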

Other observations

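The tests chosen only after their results were seen are the splits of the libraries for genes, for lists and for CLP-changed genes with an opposite gallic acid call, the correlation of CLP with gallic acid replicate 7 with other libraries, its estimate from genes that rose, and the assignments for opposite signs.

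Members of further lists changed with CLP. Lists with fewer than 5 tested members had no camera test, and only counts are given for them. Of 4 interferon-response genes 3 fell and 1 rose in CLP against sham: the antiviral Rsad2 by -1.61 ± 0.32 on the log2 scale, Gbp6 by -1.91 ± 0.52 and Ifit3b by -1.22 ± 0.42 (edgeR adjusted p = 0.00154, 0.00799 and 0.0239, Gbp6 at -2.51 without CLP replicate 3, the call of Ifit3b lost without sham replicate 4 at 0.0561 and without CLP replicate 2 at 0.0803), while the nucleic acid sensor Zbp1 rose 3.83-fold. All 4 coagulation genes rose, with Cpb2 at 3.18-fold, the kininogen Kng1 at 2.72-fold and the thrombomodulin gene Thbd at 3.28-fold. Of 5 complement genes 3 rose, among them the regulators C4bp (2.12-fold) and Serping1 (2.95-fold), and C8g fell (log2 change -0.78 ± 0.27, adjusted p = 0.0269), a call lost without any of 4 single libraries (adjusted p 0.0502 to 0.0802). The list did not pass (camera adjusted p = 0.193; adjusted p = 0.254 with an estimated correlation). Of 4 cell death genes 3 rose, with the necroptosis kinase Ripk3 at 2.69-fold and the death receptor Fas at 2.16-fold.

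Of 3 lipogenesis genes 2 fell and 1 did not pass. The malic enzyme Me1 and the desaturase Scd1 fell by 1.42 ± 0.24 and 3.18 ± 1.08 on the log2 scale (adjusted p = 0.000731 and 0.023, the latter 0.0603 without sham replicate 1), and the cholesterol synthesis gene Sqle rose 3.38-fold (adjusted p = 0.0128, 0.051 without sham replicate 2 and 0.106 without CLP replicate 1, where its log2 change was 0.774 against 1.755 with all libraries). Of 4 periportal genes 3 fell, with Etnppl at -3.41 ± 0.57 (-2.79 without sham replicate 1), while Ctsc rose 2.79-fold. All 3 erythroid genes fell, with Alas2 at -1.91 ± 0.37, Hba-a2 at -1.20 ± 0.29 and Hba-a1 at -1.23 ± 0.30. Of 4 stellate cell and fibroblast markers 2 rose and 2 fell (1 and 2 under median-of-ratios scaling and without scaling), with Timp1 at 11-fold higher (log2 change 3.46 ± 1.00, 5.17 without sham replicate 1) and the smooth muscle Tagln at -1.48 ± 0.41, and the protease inhibitor Slpi, listed as a mesothelial marker, rose 4.2-fold. The 2 listed pancreas markers were Ttr, also a major hepatocyte product, at -1.02 ± 0.29, and Cela1 at -1.69 ± 0.34.

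CLP with gallic acid replicate 7 lay nearer the sham groups than the other CLP libraries. For an admixture of sham liver RNA, which would give 1 share for all genes, genes that fell at least 8-fold with CLP implied a median sham share of 12.6% (95% bootstrap interval 8.05 to 22.1) and genes that fell 2- to 4-fold 24.2% (20.5 to 31.5), and these intervals overlapped, as an admixture predicts. Genes that rose at least 8-fold implied 53.7% (46.1 to 59.1), above the genes that fell under every scaling, which argues against an admixture as the whole cause and leaves a small one open. A mislabelled sham library is argued against by its correlation of at least 0.936 with every CLP library, against at most 0.914 with the sham libraries. A milder CLP response, or a larger effect of gallic acid, in that library stays open and untested.

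In CLP with gallic acid against CLP, 156 genes (12.1%) had an unadjusted p under 0.05, more than the 5 in 100 expected with no effect. Scaling of the libraries is argued against, since the lowest number under the other scalings was 162. Selection of the listed genes on these libraries stays open: simulations without a gallic acid effect gave a mean of 58.6 genes without the selection and 132 (104 to 162) with it. As many as observed came in 2 of 100 with it, which is few for selection alone, but the highest simulated number lay above the observed one, so that selection and an effect of gallic acid on CLP liver cannot be told apart. In sham mice 88 of 100 such simulations gave at least the observed 122. The simulations match the data only in part. In CLP against sham they called 945 to 1020 genes with the selection and 675 to 777 without it, against 804 observed.

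The hypothesis that gallic acid moves the same genes in both states was not borne out: its log2 changes in sham and in CLP mice correlated at r = 0.0261, and 35 of 100 splits of the gallic acid labels gave a value as high (other splits -0.165 to 0.241). The hypothesis that gallic acid reduces the whole CLP response was not borne out either by its rule, a slope below that of equal changes in every fit. The slope was 0.953 in the main fit and reached 1.137 with CLP with gallic acid replicate 7 left out. With a jackknife SD of 0.296, these slopes cannot tell a reduced response from an unchanged one. The CLP effect and the gallic acid effect in CLP mice had opposite signs in 72.8% of the genes called in CLP against sham (r = -0.439 over all tested genes), against 57.7% (53.5 to 62.3) in simulations without a gallic acid effect. That pattern rests on replicate 7: among the 20 assignments of the 6 CLP libraries 6 gave a correlation as low, and r was -0.534 to -0.336 wherever replicate 7 was in the second group and -0.0197 to 0.168 wherever it was in the first. The call of the male-biased hepatocyte list was lost without it (camera adjusted p = 0.529), and also without CLP replicate 2 (0.351) and with an estimated correlation (adjusted p = 0.803), so that it does not rest on replicate 7 alone.

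With 3 libraries against 3, no count of splits can fall under 0.05, so a low count cannot argue against another grouping. Of the 10 splits of the 6 libraries, the number with at least as many called genes, the real one included, was 1 in CLP against sham (804 calls, highest other split 1), 10 in CLP with gallic acid against CLP (0, highest other 2), 10 in sham with gallic acid against sham (0, highest other 0) and 1 in CLP with gallic acid against sham with gallic acid (848, highest other 0). For called lists it was 1 (14, highest other 11), 7 (1, highest other 6), 9 (1, highest other 7) and 2 (14, highest other 15). Most splits thus matched the single list call in each gallic acid comparison, so another grouping stays open for both calls. For CLP-changed genes with an opposite gallic acid call it was 10 (0, highest other 2). A real number of 0 is matched by every split, so nothing follows from such a count. For lists in the interaction the real number was 0, so that every one of the 100 splits gave as many (100 of 100, highest other 8) and nothing follows from it.

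Among counts from 1 to 99, 38.1% of 6003 values were multiples of 4 (35.3 to 40.8% per library), where 25% would be expected, and among 4584 high counts 24.5% were, so values that rest on low counts, such as the ratio of Mup-ps16, are read with that caution.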
